A study of Homo sapiens with 2 samples.

How the data were processed

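Total RNA from 2 cultures of Jurkat cells, a human T cell leukaemia line, was compared on 2 microarrays, 1 per group and with no replicate. Per the labels' protocols, the cells were transfected with a synthetic miRNA precursor at 40 nM and harvested 48 h later. The control group received a negative control precursor and the other group the precursor of miR-517a. Cy3-labelled cRNA was hybridised to a 1-colour Agilent whole human genome array. Samples were assigned to the groups by the labels. Per the file headers, both arrays were on 1 slide and were read in 1 scan, so slide and scan did not differ between the groups.

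The scanner files deposited by the authors give intensity values per spot, made with Agilent Feature Extraction 10.7 per the submitters' processing notes and 10.7.3.1 per the file headers. Per the file headers, the array design was 014850, its annotation build was hg18, and the extraction protocol was GE1_105_Jan09. The processed signal is an intensity from which the background was subtracted and spatial trends were removed, per the file headers, and it was not scaled between arrays. The authors also deposited a table of log2 values of the same arrays. Set against the scanner values, that table held the log2 processed signal less 1 constant per array, 10.48 for the control array and 10.29 for the miR-517a array. This held for 40923 and 40925 of 41000 probes within 0.01, and the medians of the columns were -3.20 and -3.19. How the authors chose the constant is not given in the sources used here. The scale and direction of the table were settled by that match.

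Values were taken as log2 of the processed signal minus the 75th percentile of each array's non-control spots, which corresponded to signals of 1560.0 on the control array and 1376 on the miR-517a array. Of 45015 spots per array, 1639 control spots were left out, as were spots with an outlier flag, 76 on the control array and 79 on the miR-517a array. No spot was saturated. Spots of 1 probe were averaged, which left 40957 of 41000 distinct probes. A probe was used where at least 0.5 of its spots were well above background, by the software's own flag, on both arrays. The difference of a gene was the median log2 difference, miR-517a minus control, over its probes. Probes were named through the RefSeq accession in the files, matched without versions to a RefSeq gene table of assembly GRCh38.p14. The table's build differs from that of the array design, so no coordinates are given. The match named 24761 probes (60.5%) as 16947 genes, and 16196 probes stayed unnamed. Of the named genes, 14151 were measured on both arrays, 9255 by 1 probe and 4896 by 2 or more. A gene above background on 1 array alone has a bound, given as at least N-fold. It was computed from the brighter array against the higher of the dim probe's own signal and the lowest signal well above background on the dim array, 8.39 on the control array and 8.54 on the miR-517a array.

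The precision within an array was read from 257 probes printed 10 times with at least 8 usable spots. For each gene, the spot SD is the median SD of the log2 difference over 50 of these probes. They were the nearest in signal among the 215 well above background on both arrays, so probes at background did not enter. The spot SD covers the spread between spots of 1 array pair and not the spread between cultures. With 1 array per group no test of a difference was possible, and no p-value is given. The counts are of genes at least 2-fold apart, a log2 difference of 1. A gene list was described by the median difference of its measured members and the percentile of that median among 10000 random lists of the same size, drawn in 10 bins of signal. Such a percentile describes these 2 arrays and not the conditions. Of 591 list members, 575 were matched to a probe.

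The groups, the designs, the alternatives, the 27 gene lists and the rule for naming genes were chosen before the data were examined. The rule named, in each direction, up to 12 genes with the largest difference. Each had to differ at least 2-fold with both the processed signal and the normexp correction, with no probe on the other side of 0 and a mean signal above the 25th percentile of measured probes. It further named the 4 largest bounds in each direction, PRKG1, TNIP1 and PTK2B from published work on the miR-517 family, and up to 4 members with the largest difference in each list. The lists were T cell receptor signalling, T cell activation and immediate early genes, T-ALL and T cell transcription factors, cGMP and PKG signalling, NF-kB pathway and targets, type I interferon response, miRNA pathway, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, unfolded protein and integrated stress response, heat shock response, cholesterol biosynthesis and uptake, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, replication-dependent histones, cytokine and chemokine receptors, housekeeping genes, markers of B cells, monocytes and macrophages, NK and cytotoxic cells, erythroid cells, fibroblasts and epithelia, and trophoblast, and the named miR-517 targets.

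The alternatives chosen in advance were normexp background correction with an offset of 50, no background subtraction, quantile normalization, median centring, loess on mean signal with a span of 0.3, no filter and a stricter filter on dim probes, the brightest probe per gene, the authors' deposited log2 table, and thresholds of 1.5-fold and 3-fold. The plan named the mean spot signal for the normexp and no-subtraction settings. The median spot signal was used, because the scanner files list no mean signal. Scaling by the added spike-in probes, leaving out spots that lie within 4 rows and 2 columns of a spot differing 4-fold, and counting only genes whose every probe passed the threshold were added after seeing the data. A planned comparison of genes with and without a seed site for the miRNA was not run, since no 3' UTR sequences were used here, and its part of the naming rule named no gene.

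The counting step was tested on simulated data for 14151 genes. It recovered 50 of 50 genes at each simulated log2 difference of -2, -1.3, 1.3 and 2, and called 0 of 13951 unchanged genes. A simulated list of 30 genes shifted by 0.1 stood at percentile 100 and an unshifted list at percentile 49.6. The simulated noise was the spot SD alone, without spread between cultures, single-spot outliers or local patches. The simulation therefore says nothing of false calls on the real arrays. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the normexp correction.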

Results

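Gene expression was measured in Jurkat cells, a human line derived from a T cell acute lymphoblastic leukaemia, 48 h after transfection with the precursor of miR-517a or with a negative control precursor. miR-517a is a miRNA made in the placenta, and the series set out to find its target genes in immune cells that it can reach from the placenta. There was 1 array in each group, so no difference has a replicate check. The control array had 34799 spots (80.2%) well above background and the miR-517a array 34468 (79.5%) of 43376. Across the 31859 probes above background on both arrays, r was 0.997 across probes, which are not independent replicates. Of the 14151 genes measured on both arrays, 12909 (91.2%) differed by less than 1.2-fold. The central 95% of genes ran from -0.29 to 0.41 in log2 difference, miR-517a minus control. Among 215 repeat-printed probes above background on both arrays, the SD of that difference between spots had a median of 0.057.

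PRKG1, which encodes a cGMP-dependent protein kinase and was named in published work as a target of miR-517a in this line, was 3.46-fold lower on the miR-517a array. Whether that work drew on these same arrays is not known here, so the value is not an independent check of it. The log2 difference of PRKG1 was -1.79, with a spot SD of 0.18, a value shared with dimmer genes such as NR4A2 and FOS. Over the 1000 probes nearest to it in signal with no 4-fold neighbour, the SD of the difference was 0.31. The signal was 42.0 on the control array and 10.68 on the miR-517a array, with the software's own error estimates of 4.66 and 2.32. TNIP1, an inhibitor of NF-kB signalling named as a target of the same miRNA family, differed by -0.025, with probes at -0.086 and 0.036 and a spot SD of 0.054. PTK2B, a relative of focal adhesion kinase, differed by 0.0063 with a spot SD of 0.067. The median of these 3 named targets was -0.025, at percentile 33.9 of random lists. The PRKG1 value came from 1 of its 2 probes, as the other was not well above background on either array, with signals of 3.16 and 2.62. It was -0.38 with the normexp correction, -0.58 without background subtraction and -0.79 with no filter on dim probes.

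Across the genome, E2F7, a repressor of E2F target genes, was 46.0-fold lower on the miR-517a array, with signals of 3631 on the control array and 69.6 on the miR-517a array. LASP1, an actin-binding protein, was 106-fold higher, with signals of 53.3 and 4986. With the normexp correction the log2 difference of E2F7 was -4.50 in place of -5.52 and that of LASP1 5.69 in place of 6.73. LSM14B, an RNA-binding protein of messenger ribonucleoprotein particles, was 3.74-fold lower, with both of its probes lower at -2.96 and -0.84. In all, 23 genes were at least 2-fold higher and 17 at least 2-fold lower, 0.283% of those measured. Scaled to the added spike-in RNAs, which raised every gene by 0.20, the split was 47 higher and 12 lower.

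The naming rule was met by 6 higher and 5 lower genes. Besides LASP1, the higher genes were BHLHE23, a basic helix-loop-helix transcription factor (4.46-fold), RNF130, a ubiquitin ligase (4.16-fold), HCN2, a pacemaker cation channel (3.32-fold), SNX14, a sorting nexin (2.25-fold), and CFAP65, a cilia and flagella protein (2.15-fold). Each was measured by 1 probe, and their spot SDs ran from 0.037 for HCN2 to 0.059 for LASP1. Besides E2F7 and LSM14B, the lower genes were ANP32E, a histone chaperone (6.37-fold), PPP1R1C, an inhibitor of protein phosphatase (3.35-fold), and DLL1, a Notch ligand (3.03-fold). The probes of ANP32E lay at -5.16 and -0.18 and those of PPP1R1C at -3.48 and -0.013, so in each gene 1 probe carried the difference. DLL1 was measured by 1 probe, at -1.60.

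**Figure D1:**
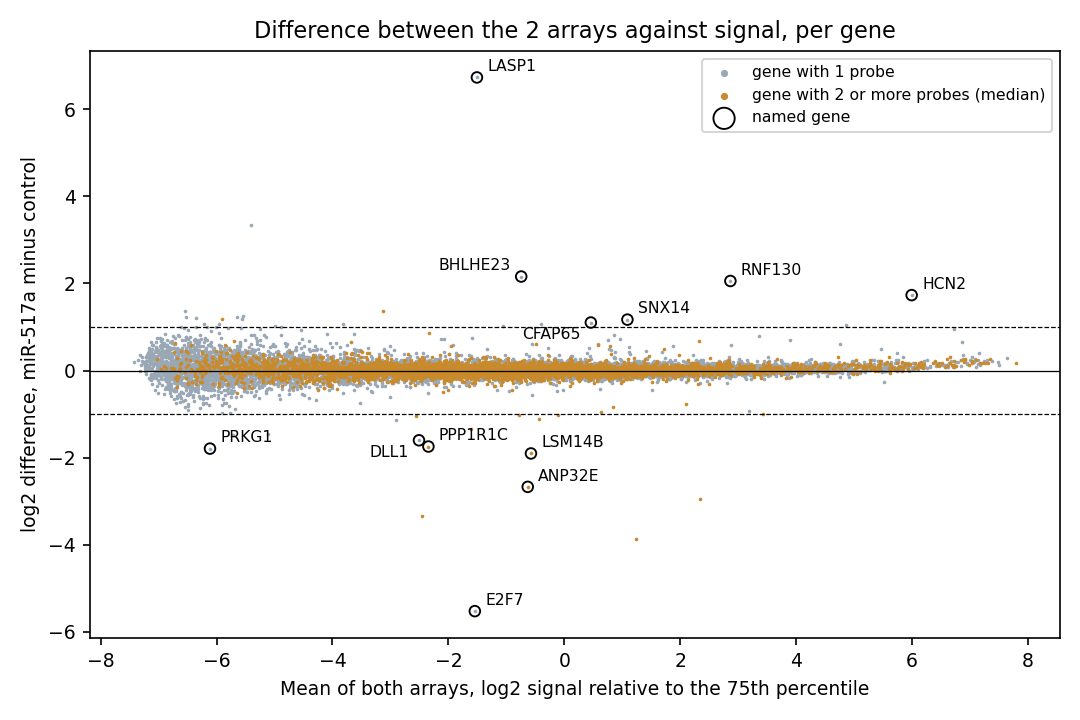
Log2 difference per gene, miR-517a minus control, against the mean log2 signal of both arrays relative to the 75th percentile, for 14151 genes measured by 1 probe (grey) or by 2 or more (orange). Dashed lines mark a 2-fold difference, and circles mark the named genes, from LASP1 at 6.73 to E2F7 at -5.52, with PRKG1 at -1.79 among the dim genes.

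Several of these spots lay close together on the array. The LASP1 spot had a neighbour with a difference of 10.92, the E2F7 and DLL1 spots had neighbours reaching 5.95, and the largest neighbouring differences were 3.605 for PPP1R1C, 3.39 for SNX14 and 3.19 for ANP32E. These 6 of the 11 genes, among them 4 of the 5 lower ones, thus lay beside a spot differing 4-fold. For LSM14B the largest difference among the neighbours was 0.38, for CFAP65 0.52, for HCN2 0.74, for BHLHE23 0.93 and for RNF130 1.08. The HCN2 spot, in row 77 of column 84, lay just outside the 4-row window around the LASP1 spot, in row 71 of that column. The spot differing by 10.92 was in row 69 of the same column. LASP1, HCN2, BHLHE23 and RNF130, 4 of the 6 higher genes, lay in the outer 6 columns on either side of the array. PRKG1 had a largest neighbour of 0.62. Of the 111 probes printed once that differed at least 2-fold, 49 (44.1%) lay beside a spot differing 4-fold, against 7.66% of all measured probes. Without such spots, 15 genes were higher and 4 lower, and with the normexp correction 7 were higher and 11 lower. Of the 23 higher genes 12 had signals below the 25th percentile, as did 3 of the 17 lower genes. Of the higher genes 21 rested on 1 probe, and of the 13 genes with 2 or more probes 9 had probes on both sides of 0.

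**Figure D2:**
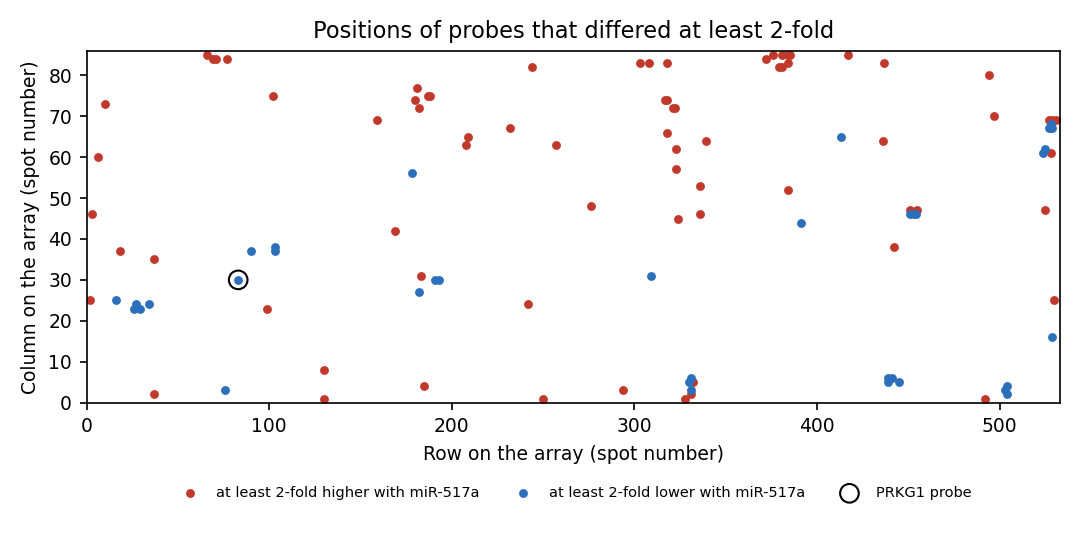
Row and column on the array, in spot numbers, of the 111 once-printed probes that were at least 2-fold higher (red) or lower (blue) on the miR-517a array. The PRKG1 probe is circled and stands apart from the others, while 39 of the probes (35.1%) lie in the outer 6 columns on either side, which hold 13.1% of all measured probes.

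Some genes were above background on 1 array alone. On the miR-517a array alone, MBD3L2 was at least 15.2-fold higher, ZNF804B, a zinc finger protein, at least 10.5-fold, TREM1, a receptor of myeloid cells, at least 9.49-fold, and KCNA6, a potassium channel, at least 7.81-fold. On the control array alone, OR51E1, an olfactory receptor, was at least 5.31-fold higher, ACVR1C, an activin receptor, at least 3.67-fold, OR8D1, another olfactory receptor, at least 2.54-fold, and RNF135, a ubiquitin ligase, at least 2.51-fold. All of these spots except that of OR8D1 lay beside a spot differing 4-fold. There were 206 genes above background on the miR-517a array alone, 25 of them with a bound of at least 2-fold. On the control array alone there were 298, 6 of them with such a bound.

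T cell genes were close to even between the arrays, and those of T cell receptor signalling and lineage control leaned lower with miR-517a. Of 28 measured genes of T cell receptor signalling, 12 were higher and 16 lower, with a median of -0.035 at percentile 0.83 of random lists, and 0.16 with spike-in scaling. BCL10, a scaffold of NF-kB activation, was at -0.23, GRAP2, an adaptor, at -0.15, PLCG1, a phospholipase, at -0.14 and the costimulatory receptor CD28 at -0.13. Of the 22 T-ALL and T cell transcription factors, 8 were higher and 14 lower, with a median of -0.065 at percentile 0.10, and 0.13 with spike-in scaling. The homeobox genes TLX1 and TLX3 stood at -0.41 and -0.39 with signals near background, TCF7, a regulator of T cell development, at -0.20 with bright signals, and NOTCH3 at 0.22. With loess on mean signal the transcription factors stayed below the central 95% of random lists at -0.068, and T cell receptor signalling lay inside it at -0.036.

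Cytokine and chemokine receptors had the lowest median of the lists outside the central 95%. Of 21 measured members, 6 were higher and 15 lower, with a median of -0.082 at percentile 0.14, but 0.018 with the normexp correction and 0.12 with spike-in scaling. IL7R, the receptor of a T cell survival cytokine, was at -0.31, but at -0.025 with the normexp correction. IL6ST, the shared receptor chain of the IL-6 family, was at 0.34, CXCR5 at 0.27 and IL21R at 0.19. With normexp these were at 0.26, 0.23 and 0.20. IL6ST and CXCR5 had signals near background, and the probes of CXCR5 lay at 0.021 and 0.51. Replication-dependent histones were lower for 16 of 24 members, with a median of -0.035 at percentile 2.17, and 0.16 with spike-in scaling. With loess they lay inside the central 95%, at -0.036. H1-5 was at -0.36 and H2AC6 at -0.23, against 0.25 for H4C3 and 0.23 for H2BC4.

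Ribosomal proteins had the highest median of any list. Of 30 members 29 were higher on the miR-517a array, with a median of 0.17 at percentile 100 of random lists, 0.026 with loess on mean signal and -0.0027 with quantile normalization. RPL38 was at 0.65, from 1 probe in the last column, and RPS6 at 0.36. RPL7 was at 0.31, with probes at 0.12 and 0.50, and RPL23 at 0.30. The 1415 brightest of all genes had a median of 0.046.

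Stress and sterol genes also leaned higher with miR-517a. Of 18 heat shock genes 14 were higher, with a median of 0.10 at percentile 99.5. The cochaperone STIP1 was at 0.50, with probes at 0.12 and 0.87, the larger difference in the last column beside spots with a median of 0.38, and CRYAB, a small heat shock protein, was at 0.25. The chaperone HSPA8 was at 0.21 over 4 probes and HSP90AB1 at 0.17 over 3 probes, which ran from -0.25 to 0.18. Of 26 genes of the unfolded protein and integrated stress response 22 were higher, with a median of 0.066 at percentile 98.8. CHAC1, which degrades glutathione, was at 0.25, the transcription factor ATF5 at 0.22 and ASNS, which makes asparagine, at 0.20. SEL1L was at 0.19, with probes on both sides of 0 at -0.080 and 0.45. Both lists stayed just above the central 95% with loess on mean signal, at 0.045 and 0.039 against upper limits of 0.042 and 0.037. The brightest of the 10 signal bins ran from 2.79 to 7.80 in scaled log2 signal, so bright members such as HSPA8 were loosely matched. Of 24 genes of cholesterol biosynthesis and uptake 18 were higher, with a median of 0.075 at percentile 99.5. SQLE, an oxygenase of the sterol pathway, was at 0.58, beside a spot differing by 2.92, HMGCS1 at 0.28 and IDI1 at 0.23, while STARD4, a sterol carrier, was at -0.20. With loess this list lay inside the central 95%, at 0.028.

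**Figure D3:**
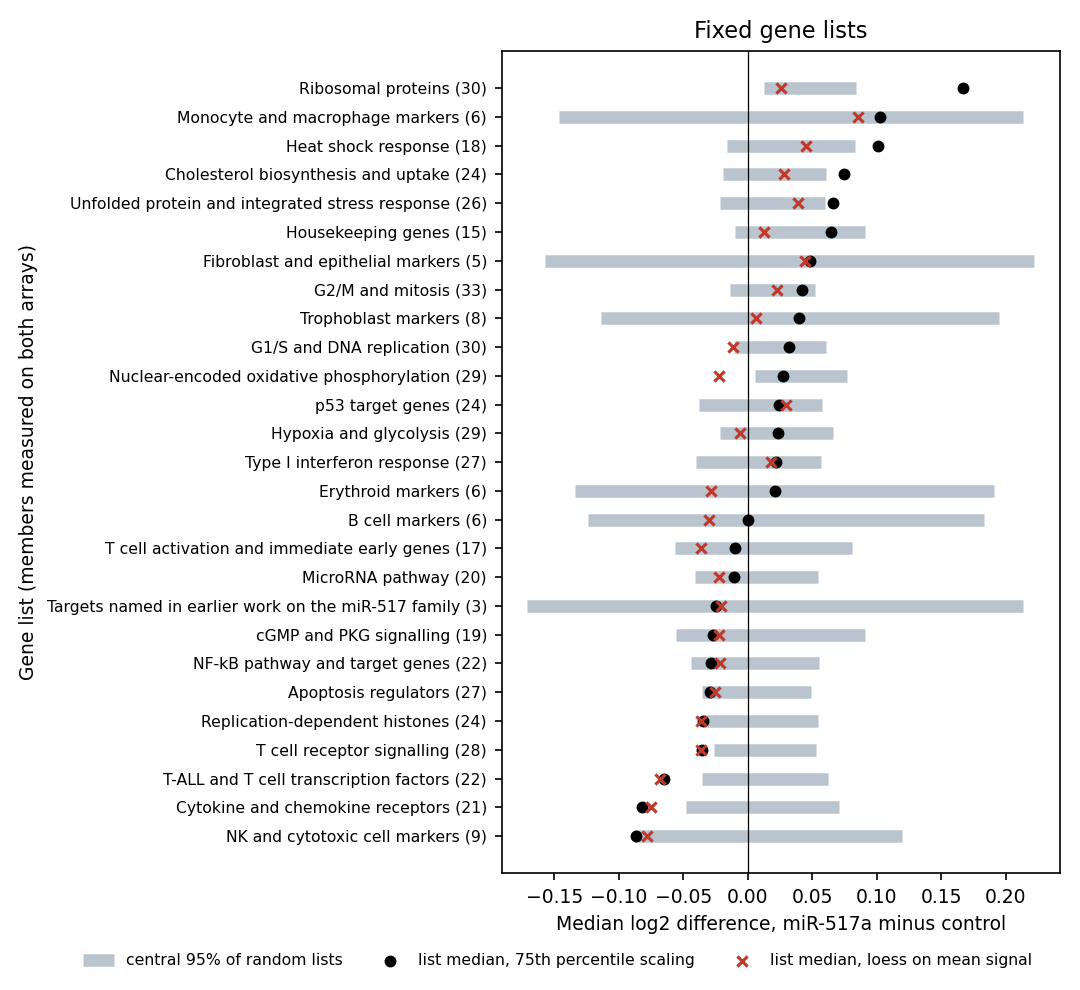
Median log2 difference of each list, miR-517a minus control, with the 75th percentile scaling (black points) and with loess on mean signal (red crosses), and the central 95% of 10000 random lists of like signal under the 75th percentile scaling (grey bars). The largest median is 0.17, for ribosomal proteins, and is -0.0027 with quantile normalization, while spike-in scaling adds 0.20 to every point.

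In all, 8 of the 27 lists lay outside the central 95% of random lists, 4 below and 4 above. The count would be 1.35 on average if each list were a random draw of genes of like signal. Members of a list can vary together, which the random lists do not reproduce, so 8 against 1.35 is no measure of an effect of the miRNA. With loess 5 of the 8 lists stayed outside. Spike-in scaling, which adds the same 0.20 to every gene, put all 27 medians above 0. No list median was further from 0 than 0.17, and PRKG1 was the single list member that differed 2-fold. Among the list members named, the sole probes of SQLE, CCNE2, TTK, CASP6, BMF, FOSB, TLX3, IFIT3, EGLN3 and HBA1 and 1 or more probes of HSPA8, COX4I1 and TNIP1 lay beside a spot differing 4-fold. The JUN probe, printed more than once and so not flagged, had at least 1 spot beside a difference of 4.12.

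The pathways around PRKG1 and TNIP1 stayed inside the central range. Of 19 genes of cGMP and PKG signalling 8 were higher and 11 lower, with a median of -0.027 at percentile 11.8. Besides PRKG1, the cyclic nucleotide-gated channel CNGA1 was at 0.62, with signals of 12.01 and 16.3, and PLN and the kinase substrate IRAG1 were both at 0.18. Of 22 genes of the NF-kB pathway 6 were higher and 16 lower, with a median of -0.028 at percentile 9.77. BCL2A1, a survival gene, was at 0.39 with probes at -0.073 and 0.85, TNFAIP2 at -0.34, NFKBIA, an inhibitor of NF-kB, at -0.19 and TNFAIP3, another inhibitor, at -0.18. With the normexp correction BCL2A1 was at 0.12, TNFAIP2 at -0.062, NFKBIA at -0.21 and TNFAIP3 at -0.0062. Apoptosis regulators had 9 higher and 18 lower members of 27, with a median of -0.030 at percentile 4.62. Among them CASP7 was at 0.22, CASP6 at -0.20, BMF at -0.19 and APAF1 at 0.18.

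Genes of the response to foreign RNA and of the miRNA machinery were near even. Of 27 type I interferon genes 18 were higher, with a median of 0.022 at percentile 72.7, and 0.088 with the normexp correction. IFI44L was at 0.43, IFIT3 at 0.34, IFI6 at 0.28 and IFIT1 at 0.24, of which IFI44L and IFIT3 had signals near background. Of 20 miRNA pathway genes 9 were higher and 11 lower, with a median of -0.011 at percentile 24.2. TNRC6C was at -0.18, AGO2, the slicing Argonaute, at -0.17, DGCR8 at -0.17 and DICER1, which cuts miRNA precursors, at -0.16. The probes of DGCR8 lay on both sides of 0, at -0.36 and 0.024. Of 17 activation and immediate early genes 8 were higher and 9 lower, with a median of -0.010 at percentile 29.0. NR4A2 was at -0.53 and FOS at -0.43, both with signals near background, while JUN was at -0.18 and FOSB at 0.20.

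Cell cycle and metabolic lists lay inside the central range too. Of 30 genes of G1/S and DNA replication 20 were higher, with a median of 0.032 at percentile 68.1, and -0.011 with loess. CCNE2, a G1/S cyclin, was at 0.32, the helicase subunit MCM3 at 0.25, RRM1 at 0.20 and DHFR at 0.14. The 4 probes of DHFR ran from -0.035 to 0.18. Of 33 genes of G2/M and mitosis 21 were higher, with a median of 0.042 at percentile 90.4, among them DLGAP5 at 0.23, HMMR at 0.19, TTK at 0.19 and MAD2L1 at 0.18. Of 24 p53 targets 14 were higher, with a median of 0.024 at percentile 73.5. RRM2B was at 0.23, CCNG1 at 0.19, ZMAT3 at -0.17 and TIGAR at -0.16, with probes at -0.30 and -0.015. Of 29 genes of hypoxia and glycolysis 18 were higher, with a median of 0.024 at percentile 56.6, and -0.0060 with loess. EGLN3, an oxygen sensor, was at -0.36, ENO1 at 0.24, with probes at 0.0062 and 0.47, P4HA1 at 0.20 and PFKL at 0.17. Of 29 genes of oxidative phosphorylation 21 were higher, with a median of 0.027 at percentile 29.3, and -0.023 with loess. COX4I1 was at 0.24, with probes at 0.0081 and 0.48, UQCRC1 at 0.16, COX5B at 0.15 and UQCRH at 0.11. Of 15 housekeeping genes 13 were higher, with a median of 0.065 at percentile 83.8, with RPLP0 at 0.26, UBC at 0.20, ACTB at 0.20 and EEF1A1 at 0.17.

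Markers of other cell types were mostly dim, and none of their lists lay outside the central range. B cell markers had a median of 0.00040 over 6 measured genes, and -0.030 with loess, with VPREB1 at -0.25, CD19 at 0.24, EBF1 at -0.15 and MS4A1 at 0.13. Monocyte and macrophage markers had a median of 0.10 over 6, with MARCO at 0.33, TYROBP at 0.22, CSF1R at 0.22 and ITGAM at -0.16. NK and cytotoxic cell markers had a median of -0.086 over 9, at percentile 2.74, with KLRB1 at 0.57, NCAM1 at -0.34, GZMB at -0.23 and GZMK at -0.19. Erythroid markers had a median of 0.021 over 6, and -0.028 with loess, with HBD at 0.27, SLC4A1 at 0.26, HBA1 at -0.26 and AHSP at -0.097. Fibroblast and epithelial markers had a median of 0.048 over 5, with KRT19 at 0.25, CLDN4 at 0.18, KRT18 at -0.090 and DCN at 0.048. Trophoblast markers had a median of 0.039 over 8, with ADAM12, a protease of placenta, at 0.56, GCM1 at 0.25, CSH1 at 0.17 and CGB3 at -0.11. The probes of GCM1 lay at 0.0066 and 0.49.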

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

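The tests on single probes, those of the slide around the PRKG1 spot and of scatter among probes like it, and that of the ribosomal genes with equally bright partners were chosen only after the results were seen, as was the reading that the comparison of all ribosomal proteins was poorly matched. The test for a defect of the PRKG1 spot and the comparison of all ribosomal proteins were fixed before their results were seen.

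Probes that no gene in the RefSeq table matched lay outside the comparisons, and 40 of 11336 such probes were at least 2-fold higher on the miR-517a array while 13 were at least 2-fold lower. The largest difference was 10.92, for probe A_24_P350126, whose signal was 62.5 on the control array and 106759 on the miR-517a array. Its largest neighbouring difference, 6.73, was that of the LASP1 spot. The added spike-in RNAs, which also lay outside the comparisons, had a median scaled difference of -0.20 over the 6 of 10 probes above background on both arrays, with a range of -0.67 to -0.088.

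The first pattern was the large differences of single probes, such as those of E2F7, LASP1 and ANP32E. A change in the mRNA was argued against as the general source for the 31 such probes with partner probes, because the partners had a median of -0.028 in the direction of the 2-fold probe, against a median size of 2.01, but it stays open for LSM14B and MCCD1, whose partners moved the same way by more than 1.5-fold. Of the 37 lower probes, 21.6% (exact 95% binomial interval 9.83 to 38.2) lay below the 25th percentile of signal. Scatter of dim probes was thus argued against as the main source of these 37. It stays open for the 74 higher probes, of which 43.2% (31.8 to 55.3) lay below that percentile. Both shares cover only probes above background on both arrays, a filter that leaves out dim probes that fell to background on 1 array. The intervals treat probes as independent, although many lay close together. Uneven local hybridization may account for a part of them, since 44.1% lay beside a spot differing 4-fold, against at most 17.1% in 1000 random placements, and 35.1% lay in the outer 6 columns on either side, against 13.1% of all measured probes. The remaining probes and the genes measured by a single probe, among them BHLHE23, RNF130 and HCN2, which lay in those outer columns, stay open.

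The second pattern was the lower signal of PRKG1, a named target of the miRNA. Uneven local hybridization that reached the neighbouring spots was argued against, because the largest difference among the 38 neighbours of the spot was 0.62. Their median of 0.0057 decides nothing, since E2F7, beside a difference of 5.95, had a neighbour median of 0.048. Unevenness limited to the PRKG1 spot itself is not excluded by these values. For scatter of dim probes, 0 of the 1000 probes nearest in signal with no 4-fold neighbour, above background or not, differed by as much either way. With such neighbours allowed 7 of 1000 did, all 7 of them beside a 4-fold difference. These counts argue against scatter only if PRKG1 was named independently of these arrays, which is not known here. Had it been picked from them for its drop, they could not decide. A defect of the single spot could not be excluded, because 1 PRKG1 probe was above background on both arrays. Of 14 other 2-fold probes with no 4-fold neighbour, 13 had partner probes under 1.2-fold in the direction of that probe. That count includes partners that moved the other way. Only 3 of the 14 were lower as PRKG1 was, and 1 of those 3, in LSM14B, had a partner at -0.84. A lower PRKG1 mRNA with miR-517a may underlie the value. With a second probe below background and no second array, it cannot be told apart from a defect of that spot. Nor can it be told apart from scatter if the gene was picked from these arrays.

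The third pattern was the higher signal of the ribosomal proteins, 29 of 30 of which were higher with miR-517a. Lists drawn from the non-ribosomal genes nearest in signal had a median of 0.11 (central 95% 0.085 to 0.13), below the ribosomal median of 0.17 and past the bound set against a trend with brightness, but 19 of the members had no equally bright genes to match, and theirs were dimmer by a median of 0.49 in log2 signal, so that comparison leaves the trend open. For the 11 members with non-ribosomal genes within 0.1 in signal, the median was 0.074, inside the range of their matching lists (0.031 to 0.12), so the trend may account for those. Loess on mean signal put the median of all members at 0.026, against an upper limit of 0.021 for random lists, and quantile normalization put it at -0.0027. For the brighter 19 members, an excess beyond the trend cannot be told apart from the trend itself, and an effect of miR-517a on them was not tested.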

How the results depend on the processing

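Scaling by the spike-in probes, leaving out spots beside a 4-fold neighbour, and requiring every probe past the threshold were chosen after seeing the data. The count of 2-fold higher genes, 23, became 7 with normexp, 8 without background subtraction, 41 with no filter, 14 with the stricter filter, 47 with spike-in scaling, 15 without spots beside a 4-fold neighbour, 132 at 1.5-fold, 5 at 3-fold and 0 with every probe of 2 or more required. The count of lower genes, 17, became 11 with normexp, 11 without subtraction, 4 without those spots, 66 at 1.5-fold, 9 at 3-fold and 0 with every probe required. The stricter filter and the left-out spots reduce the genes counted to 11517 and 13422. Under the remaining settings the counts lay within 1.5 times, from 21 to 26 higher and 12 to 20 lower. The difference of PRKG1, -1.79, became -0.38 with normexp and -0.58 without subtraction, which leave or add background in both dim signals, -0.79 with no filter, which adds the probe below background with its signals set to the lowest signal well above background on each array, and -1.59 with spike-in scaling. The stricter filter left no PRKG1 value. Spike-in scaling raised every gene by 0.20 and turned the medians of T cell receptor signalling to 0.16, T-ALL and T cell transcription factors to 0.13, histones to 0.16 and cytokine and chemokine receptors to 0.12. Normexp turned the receptors to 0.018, and the cause was not tested. Quantile normalization, which gives both arrays the same set of sorted values, turned the ribosomal proteins to -0.0027. It would also remove a real rise shared by the brightest genes, so this value does not tell such a rise from a trend. Apart from spike-in scaling, the medians of the other 6 lists outside the central range kept their sign in all 10 alternatives. These were T cell receptor signalling (-0.038 to -0.022), T-ALL factors (-0.074 to -0.014), histones (-0.039 to -0.022), the unfolded protein response (0.035 to 0.075), heat shock (0.041 to 0.11) and cholesterol synthesis (0.020 to 0.083). Median centring and the authors' log2 table shift nearly all values by a constant, with shifts of 0.0082 and 0.0032 in the median gene. They are therefore no separate check of these signs. Over all settings, 6 medians of lists outside the central range changed sign. Lists inside it changed sign 7 times with spike-in scaling and 25 times with other settings. For named genes, 260 values moved by more than the spot SD and 980 did not. The 117 values under spike-in scaling all moved, while the 117 each under median centring and the authors' log2 table did not. No paired analysis was possible because the groups share a single replicate number. A block for the slide, leaving out a replicate and the seed-site alternatives were not run, the first 2 for want of a second array per group and the last for want of 3' UTR sequences here. Signal over background limits the dimmest genes, since 7643 probes were above background on neither array and the spot SD was 0.17 in the dimmest of 4 equal groups of repeat-printed probes against 0.035 in the brightest.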

Other observations

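Genes whose separate probes moved together were chosen after their values were seen. HNRNPA0, an RNA-binding protein, was 1.70-fold lower with miR-517a, with probes at -0.78 and -0.75, a spot SD of 0.040 and signals of 8731 on the control array and 4538 on the miR-517a array. No 4-fold difference lay beside its spots. CBL, a ubiquitin ligase that dampens T cell receptor signalling, was 1.36-fold lower, with probes at -0.50 and -0.39, and at least 1 of its spots lay beside a 4-fold difference. PROX1, a homeobox transcription factor, was 1.44-fold lower at dim signals of 37.5 and 23.0. TUBA3D, an alpha tubulin, was 1.47-fold higher with probes at 0.37 and 0.74. KRTAP2-4, a keratin-associated protein, was 1.505-fold higher with probes at 0.48 and 0.70.

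Among the 4896 genes with 2 or more probes, every probe was at least 1.5-fold lower for 2 genes, LSM14B and HNRNPA0, and at least 1.5-fold higher for 1 gene, MCCD1. MCCD1 was dim, with signals of 17.3 and 34.4, and at least 1 of its spots lay beside a 4-fold difference. When probes were dealt again at random to genes 100 times, the means were 0.11 lower and 0.30 higher, and the highest lower count was 1. At a log2 difference of 0.3, 13 genes were higher with every probe and 5 were lower, against means of 7.43 and 3.82 and highest values of 13 and 9 in the random deals. The counts at 0.3 therefore did not exceed the highest random deal. Probes of 1 gene can also share sequence or binding with other transcripts, which was not examined here.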
